A study of Mus musculus with 12 samples.

How the data were processed

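Brain RNA of 12 male C57BL/6 mice was measured with the nCounter Glial Profiling Panel, which counts fluorescent barcodes bound to the transcripts of a fixed set of genes without amplification. Per the labels' protocols, the middle cerebral artery was occluded for 50 min and then released (tMCAO) or the surgery was a sham, brains were taken 3 days later, and RNA was extracted from TRIzol homogenates. The deposited series value table holds raw counts, whole numbers for 770 genes and 14 control probes per mouse. The counting software and any background step were not given in the sources used here. Of the 770 genes, 13 are the panel's housekeeping genes, and the 757 endogenous genes were tested. The 14 control probes, 8 negative and 6 positive, stayed out of the library totals and the tests. Gene symbols are those of the table; 765 of 770 matched a RefSeq gene table of assembly GRCm38.p6, which served for names only, and 5 did not. A further 2 tables of values normalised by the authors were not used, because their samples carry running numbers that match no label: 11 sample names in each table could be given to no mouse. Probes of this kind can bind transcripts of near-identical paralogues, such as those of the H2, Fcgr and C4 families, which the counts do not separate.

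Groups were taken from the group characteristic of the labels: 4 floxed mice after sham surgery, 4 floxed mice after tMCAO and 4 CD73ko mice after tMCAO, each mouse a separate sample. The 3 pairs of groups were compared. The tests of the 3 comparisons, the gene lists and the naming rule were fixed before the data were examined, on the assumption that the values would be normalised log2 expression tested with limma. The table used here holds counts, for which the plan named edgeR, and limma on log2(scaled count + 1) became an alternative.

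The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling over the endogenous genes, one coefficient per group over all 12 mice, and Benjamini-Hochberg adjustment over 757 genes within a comparison at 0.05. Adjusted p-values of single genes are edgeR's unless another tool is named. The standard error of a log2 fold change is its absolute value over the square root of F, and 95% intervals use the model's total of 14.4 degrees of freedom. Normalised counts are counts scaled to the mean effective library size. A gene was above background when it exceeded the mean of the negative control probes plus 2 SD in at least 3 of 4 mice of some group, which 712 genes did and 45 did not. Where a called gene was above background in fewer than 3 of the 4 mice of its lower group, its fold is given as a lower bound: the mean log2(scaled count + 1) of the higher group against that of the lower group with each count raised to the scaled background limit of its library. This treatment of background was chosen after the data were seen. Total counts per library are the depth behind each value, and the median standard error of a log2 fold change of floxed tMCAO against sham was 0.223 over the 252 genes of lowest level and 0.0715 over the 252 of highest level.

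Gene lists, 27 in number and fixed beforehand, covered microglial and astrocyte states, other brain cell types, blood-derived immune cells and pathways of inflammation, purine signalling and stress; the 22 with at least 4 measured members were tested against the other panel genes with limma's camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. The panel is rich in glial and immune genes, so the reference is this panel and not the genome. Camera was repeated with an estimated correlation, and fry asked whether a list's own genes moved one way. List means per mouse are averages over members of log2(scaled count + 1) minus the sham mean, compared by an exact two-sided permutation test over 70 assignments. With 22 lists the adjusted value can pass only when at least 13 lists reach the smallest p, 0.0286, so the number of lists passing this test can jump to 0. The panel's housekeeping genes were a check of the scaling, and their mean after TMM lay between -0.04 and 0.14 of the sham mean (log2).

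Genes were named by rule: in each comparison the 10 highest and the 10 lowest log2 fold changes among called genes whose groups did not overlap, the 5 smallest p-values where fewer than 5 genes passed, and in each list described up to 4 members with the smallest p and up to 2 called members that moved against the list. Genes outside the rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here. The rule also named Nt5e, which the panel does not count. The simulations of unchanged groups used 100 draws.

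Alternatives were median, housekeeping and quantile scaling, DESeq2's size factors, DESeq2 1.42.0 and limma as tests, filters on low counts, a pseudocount of 10, stricter thresholds, only the 2 groups compared, a block on the replicate number, and each mouse left out. The steps were tested on simulated counts with 200 changed genes of 757, each gene drawn independently, and the rates hold for that setting. For floxed tMCAO against sham, 95.5% of 2-fold changes were recovered and 9 of 192 calls were false; for CD73ko against floxed tMCAO, 94.0% and 8 of 187; for CD73ko tMCAO against sham, 97.0% and 5 of 188. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.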

Results

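The expression of 770 mouse genes was counted in whole brain total RNA from 12 individual male C57BL/6 mice with the nCounter Glial Profiling Panel, a hybridisation assay that counts barcoded probes of a fixed gene set. Brains were taken 3 days after 50 min of transient middle cerebral artery occlusion (tMCAO), a model of ischaemic stroke, or after sham surgery. CD73, the product of Nt5e, is a surface enzyme that converts extracellular AMP to adenosine. The 3 groups of 4 mice were floxed control mice after sham surgery, floxed control mice after tMCAO and CD73ko mice after tMCAO. A CD73ko group with sham surgery was not analysed here, so an effect of surgery within CD73ko mice could not be estimated. Nt5e was not among the genes counted, so the knockout could not be checked from these counts. The total count over the 770 genes lay between 724655 and 848853 in 11 libraries, and it was 293589 in flox sham replicate 4. Of the 757 endogenous genes, 712 were above the background of the negative control probes in at least 3 of the 4 mice of some group. The labels give each library as a separate mouse, and no pair of libraries in a group agreed within counting noise (lowest chi-square per degree of freedom 1.73), which a library deposited again would do.

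The first comparison, of floxed mice after tMCAO with floxed mice after sham surgery, measured the response of the control genotype to surgery. The genes with the largest rises included genes of phagocytic microglia and macrophages. Lgals3, which encodes galectin-3, rose from 27.6 ± 6.34 to 340.3 ± 27.4 normalised counts (mean ± SD, n = 4 mice each), a log2 fold change of 3.65 ± 0.33 (estimate ± SE). Spp1, which encodes the secreted protein osteopontin, rose from 365 ± 12.8 to 3722 ± 351 normalised counts, a log2 fold change of 3.35 ± 0.35. The next largest rises among genes above background in the shams were those of Gpnmb (3.22 ± 0.40), Serpina3n (2.93 ± 0.36), Lyz2 (2.65 ± 0.40), Lilrb4a (2.56 ± 0.29) and Cd68 (2.47 ± 0.20), as log2 fold changes ± SE. Tgm1, Cst7 and Msr1 were above background in 0 of 4 shams and in all 4 tMCAO mice, so their rises were lower bounds against the background limit, at least 6.76-fold higher for Tgm1, at least 3.51-fold for Cst7 and at least 2.79-fold for Msr1. Cst7 encodes cystatin F, an inhibitor of lysosomal cathepsins, Lyz2 encodes a lysozyme, Msr1 a scavenger receptor and Cd68 a lysosomal glycoprotein of macrophages and microglia. Among these 10 genes the edgeR quasi-likelihood adjusted p was at most 0.000239, and all 4 tMCAO mice lay above all 4 sham mice.

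Within the gene lists, markers of disease-associated microglia rose for 16 of 23 measured members, among them Tyrobp (1.84 ± 0.19), an adaptor of the receptor TREM2, and the cathepsin gene Ctsd (1.49 ± 0.16). The mean of this list per mouse was 1.24 ± 0.12 above the sham mean (log2, SD, n = 4), or 1.17 with the 4 members not above background in the shams raised there to the background limit. Of the phagocytosis and lysosome list, 12 of 13 members rose, with Ctss (1.44 ± 0.15) and Grn (1.16 ± 0.13), the progranulin gene, beside Cd68. Of the complement list, 5 of 10 rose, with C3ar1 (2.39 ± 0.21), the receptor of C3a, and the C1q subunit genes C1qa (1.62 ± 0.15), C1qb (1.70 ± 0.17) and C1qc (1.82 ± 0.16). Of the monocyte and macrophage list 5 of 6 rose, with Cd84 (1.98 ± 0.26), and of the innate and Fc receptor list 6 of 10 rose, with the Fc receptor genes Fcgr1 (1.68 ± 0.21) and Fcgr4, which was above background in 1 of 4 shams and at least 2.78-fold higher after tMCAO. Homeostatic microglia markers rose for 11 of 20 members, with Fcrls (1.93 ± 0.22) and Csf1r (0.64 ± 0.12), the receptor of colony-stimulating factor 1. The numbers adjusted over the list alone were 16, 13, 6, 5, 6 and 11 in the order given. Camera gave these lists adjusted p-values between 5.79e-15 for phagocytosis and lysosome and 0.000453 for homeostatic microglia. With an estimated correlation the adjusted p = 0.118 for disease-associated microglia, adjusted p = 0.118 for phagocytosis and lysosome, adjusted p = 0.118 for complement, adjusted p = 0.143 for monocytes and macrophages, adjusted p = 0.143 for innate and Fc receptors and adjusted p = 0.223 for homeostatic microglia, so none of these calls held.

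Genes of the reactive astrocyte lists rose as well, though whole brain RNA does not show which cells they came from. Of the measured members, 5 of 10 A1 genes and 1 of 12 A2 genes also stand in another tested list. H2-D1 and Psmb8, for example, are also in the antigen presentation list. All 3 measured pan-reactive markers passed: Gfap, the intermediate filament gene of astrocytes, rose from 937 ± 175 to 3824 ± 688 normalised counts (mean ± SD, n = 4 mice each), Vim (1.89 ± 0.18) encodes vimentin, and the third was Serpina3n. Of the A1 astrocyte list 4 of 10 rose, with Srgn (1.30 ± 0.19), H2-D1 (0.62 ± 0.11) and Psmb8 (0.76 ± 0.20), a subunit gene of the immunoproteasome, and of the A2 list 6 of 12 rose, with Emp1 (1.28 ± 0.26) and Cd14 (1.09 ± 0.23) beside Tgm1; adjusted over the list alone the numbers were 4 and 8. The camera adjusted p = 0.0295 for A1 and adjusted p = 0.024 for A2, against adjusted p = 0.223 and adjusted p = 0.354 with an estimated correlation. The A1 call was lost without flox tMCAO replicate 3 (adjusted p = 0.112). The A2 call was lost without flox sham replicate 3 (adjusted p = 0.0699) or flox tMCAO replicate 3 (0.0514). None of the 7 homeostatic astrocyte markers passed, the one with the smallest p being Aldh1l1 (0.24 ± 0.12, adjusted p = 0.195).

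Among cytokine and chemokine genes, 5 of 15 measured members rose and 1 fell (8 passed adjusted over the list alone). Ccl12 (1.97 ± 0.24) and Ccl2, which encode monocyte-attracting chemokines, and Tgfb1 (1.15 ± 0.18) rose beside Spp1. Ccl2 was above background in 1 of 4 shams and at least 4.29-fold higher after tMCAO. Cx3cl1 (-0.62 ± 0.13), which encodes the neuronal chemokine fractalkine, fell. This list's camera adjusted p = 0.0332, and adjusted p = 0.359 with an estimated correlation. It was lost without flox sham replicate 3 (adjusted p = 0.0699), flox tMCAO replicate 3 (0.0581) or flox tMCAO replicate 4 (0.0631). Of the antigen presentation list 4 of 7 rose (4 adjusted over the list alone), with B2m (0.78 ± 0.10), the light chain of class I molecules. Its camera adjusted p = 0.024, and adjusted p = 0.359 with an estimated correlation. Of the interferon response list 3 of 7 rose (3 adjusted over the list alone), with Irf8 (1.12 ± 0.27), a transcription factor of microglia and macrophages, and the list did not pass camera (adjusted p = 0.28). Of 3 cell cycle genes 2 rose, among them the proliferation marker Mki67 by 1.78 ± 0.28 on the log2 scale, and the number that rose was 1 without flox sham replicate 3, 1 without flox tMCAO replicate 1 and 1 without flox tMCAO replicate 2.

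Genes that fell did so by less than 2-fold. The largest fall was that of the immediate early gene Egr1 (-0.73 ± 0.16). Kcnv1 (-0.59 ± 0.16), Chrm3 (-0.52 ± 0.12), Grin2a (-0.52 ± 0.09), Adrb1 (-0.49 ± 0.11), Rasgrp1 (-0.44 ± 0.07) and Tbr1 (-0.44 ± 0.09) also fell; Chrm3 and Adrb1 encode a muscarinic and an adrenergic receptor, Grin2a a subunit of the NMDA receptor, and Tbr1 a transcription factor of cortical excitatory neurons. In the neuron list 10 of 23 members fell and none rose (11 passed adjusted over the list alone), with Gad1 (-0.28 ± 0.07), which encodes a GABA-synthesising enzyme, beside Grin2a and Tbr1. The number of neuron genes that fell was 5 without flox sham replicate 1, 6 without flox sham replicate 3 and 6 without flox tMCAO replicate 1. Camera gave the neuron list adjusted p = 0.000218, and adjusted p = 0.192 with an estimated correlation. Cd4 and Eomes, 2 members of the lymphocyte and NK cell list with sham means of 40.6 and 63.9 normalised counts, fell by 0.60 ± 0.20 and 0.71 ± 0.24 on the log2 scale. The cells that these transcripts came from were not examined. The Cd4 call was lost without flox sham replicate 1 (adjusted p = 0.127), flox sham replicate 2 (0.0677), flox sham replicate 3 (0.0721), flox tMCAO replicate 3 (0.0623) or flox tMCAO replicate 4 (0.107). The Eomes call was lost without flox sham replicate 1 (adjusted p = 0.0981), flox sham replicate 2 (0.0772), flox sham replicate 3 (0.109), flox tMCAO replicate 1 (0.0816), flox tMCAO replicate 2 (0.0541), flox tMCAO replicate 3 (0.0559) or flox tMCAO replicate 4 (0.117). The lymphocyte list as a whole, of which 6 of 19 members were above background, had 2 members that fell, 0 adjusted over the list alone, and camera adjusted p = 0.0687.

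Markers of other cell types were examined in the same way. Of 14 oligodendrocyte and myelin genes, 1 passed, Mbp (0.28 ± 0.06, adjusted p = 0.00252), which encodes myelin basic protein, and camera gave adjusted p = 0.615. The number of called members was 4 without flox tMCAO replicate 3. The list mean of flox tMCAO replicate 3 was -0.33 while the other 3 mice averaged 0.24. Of the endothelial list 3 of 11 passed, Esam (0.46 ± 0.13), Pecam1 (0.63 ± 0.20) and Nostrin (0.69 ± 0.22), with 4 adjusted over the list alone and camera adjusted p = 0.254. The mean of this list per mouse lay 0.27 above the sham mean (log2, exact permutation adjusted p = 0.0393). The Esam call was lost without flox sham replicate 1 (adjusted p = 0.0516) or flox sham replicate 2 (0.0541). The Pecam1 call was lost without flox sham replicate 1 (adjusted p = 0.0862), flox sham replicate 2 (0.076), flox tMCAO replicate 1 (0.0579) or flox tMCAO replicate 3 (0.0941). The Nostrin call was lost without flox sham replicate 2 (adjusted p = 0.112), flox sham replicate 3 (0.0881), flox sham replicate 4 (0.0543), flox tMCAO replicate 2 (0.0517), flox tMCAO replicate 3 (0.101) or flox tMCAO replicate 4 (0.0589). In the purine list, which holds genes of extracellular nucleotide breakdown and purine receptors, 1 of 12 passed, Entpd1 (0.51 ± 0.12, adjusted p = 0.00657), which encodes CD39, the enzyme upstream of CD73; the number that passed was 2 without flox tMCAO replicate 3. The adenosine receptor genes, chosen after their values were seen, had log2 fold changes ± SE of 0.12 ± 0.12 for Adora1, -0.05 ± 0.22 for Adora2b and 0.35 ± 0.38 for Adora3, none past the threshold.

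In the smaller lists, the haem oxygenase gene Hmox1 (1.51 ± 0.28) rose among 7 hypoxia and glycolysis genes, whose median log2 fold change of -0.10 and camera direction were negative and whose mean of 0.14 was positive (camera adjusted p = 0.738). Of 4 cholesterol and lipid genes Fabp5 (0.50 ± 0.11), a fatty acid binding protein gene, and Abca1 (0.53 ± 0.12), a cholesterol exporter gene, rose (camera adjusted p = 0.169). Of 4 DNA damage and apoptosis genes Bax (0.38 ± 0.11) rose (camera adjusted p = 0.567), and of 5 oligodendrocyte progenitor genes Bcas1 (0.33 ± 0.10) rose (camera adjusted p = 0.649). Adjusted over the list alone the same numbers passed, 1, 2, 1 and 1. The Bax call was lost without flox sham replicate 1 (adjusted p = 0.0511), flox sham replicate 3 (0.0647), flox tMCAO replicate 2 (0.051) or flox tMCAO replicate 4 (0.0654). The Bcas1 call was lost without flox sham replicate 1 (adjusted p = 0.0656), flox sham replicate 2 (0.0804), flox sham replicate 3 (0.0623), flox tMCAO replicate 1 (0.0692), flox tMCAO replicate 2 (0.0681) or flox tMCAO replicate 4 (0.0634). Egr1 was the one gene that fell among 4 immediate early and heat shock genes (1 adjusted over the list alone, camera adjusted p = 0.28). None of 2 neutrophil and 3 NF-kB and inflammasome genes passed.

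In all, 167 of 757 genes passed an edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 107 higher and 60 lower after tMCAO; 54 of the higher genes and none of the lower ones changed at least 2-fold. Of these 54, 9 were above background in fewer than 3 shams, and 8 of the 9 were at least 2-fold higher against the background limit. The 4 tMCAO and 4 sham mice did not overlap for 191 genes (chance gives 2.86% of genes), among them 145 of the 167. The split between higher and lower calls depended on the scaling: it was 97 and 106 with each sample centred on its median, 90 and 95 centred on the housekeeping genes, and 68 and 106 after quantile normalisation. Camera called 11 of 22 lists, 10 higher and the neuron list lower, none of which passed with an estimated correlation, and fry, which asks only whether a list's own genes moved one way, called 16. The list means per mouse differed for 16 lists (exact two-sided permutation test, adjusted p = 0.0393, p = 0.0286, the smallest that 4 against 4 mice can give). Of these 16 lists, 15 were higher and 1 lower; with any one sham mouse left out, or centred on the housekeeping genes, 0 lists passed.

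**Figure D1:**
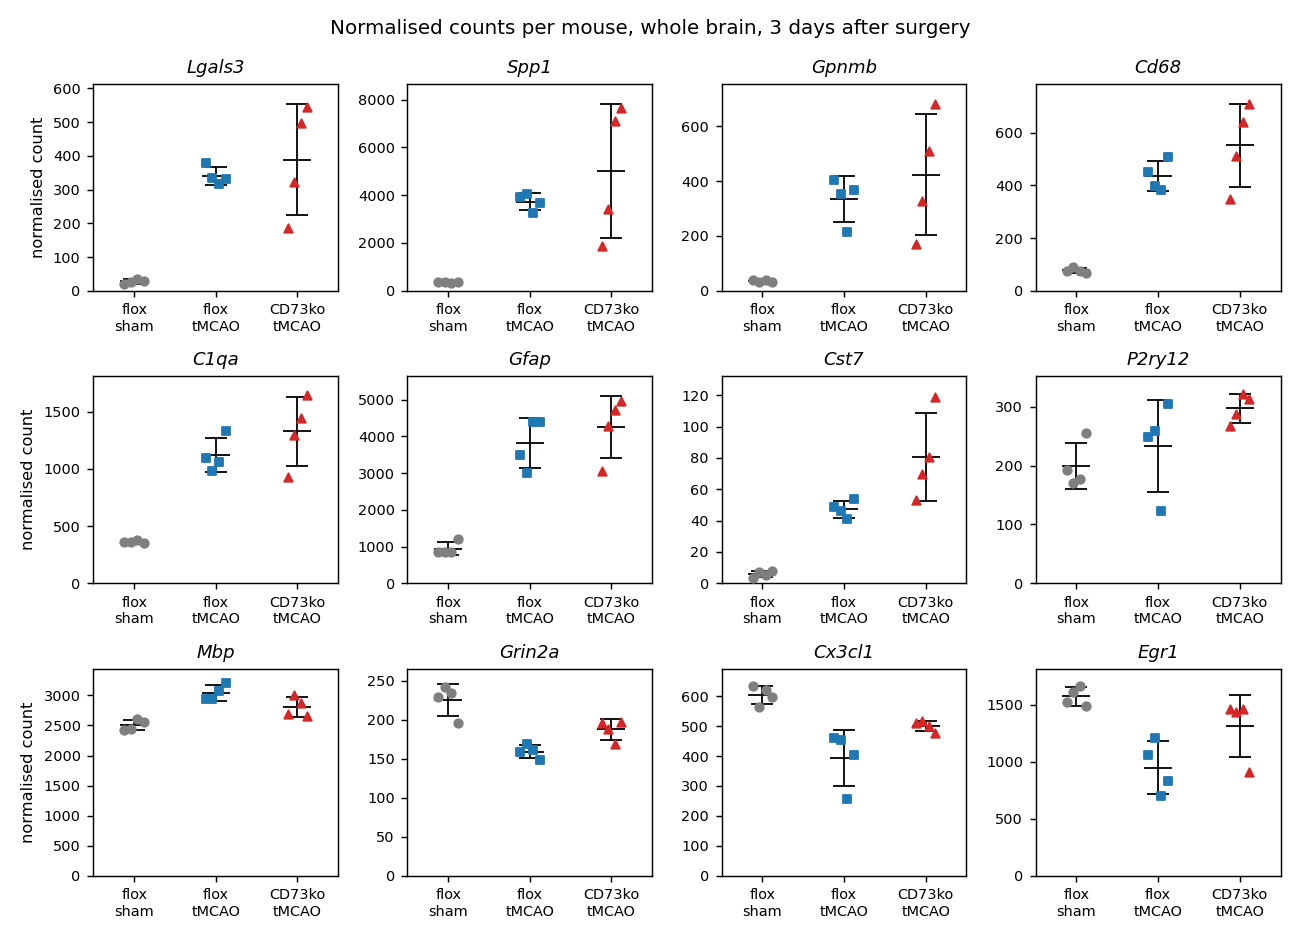
Normalised counts (y axis, linear, from 0) of 12 genes in each mouse, grouped on the x axis as floxed sham (grey circles), floxed tMCAO (blue squares) and CD73ko tMCAO (red triangles). The bars give the mean ± SD of 4 mice. Lgals3, Spp1, Gpnmb, Cd68, C1qa, Gfap and Cst7 are higher in all 4 mice of both tMCAO groups than in all 4 shams, where Cst7 was not above background; Grin2a, Cx3cl1 and Egr1 are lower in floxed tMCAO than in sham mice.

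**Figure D2:**
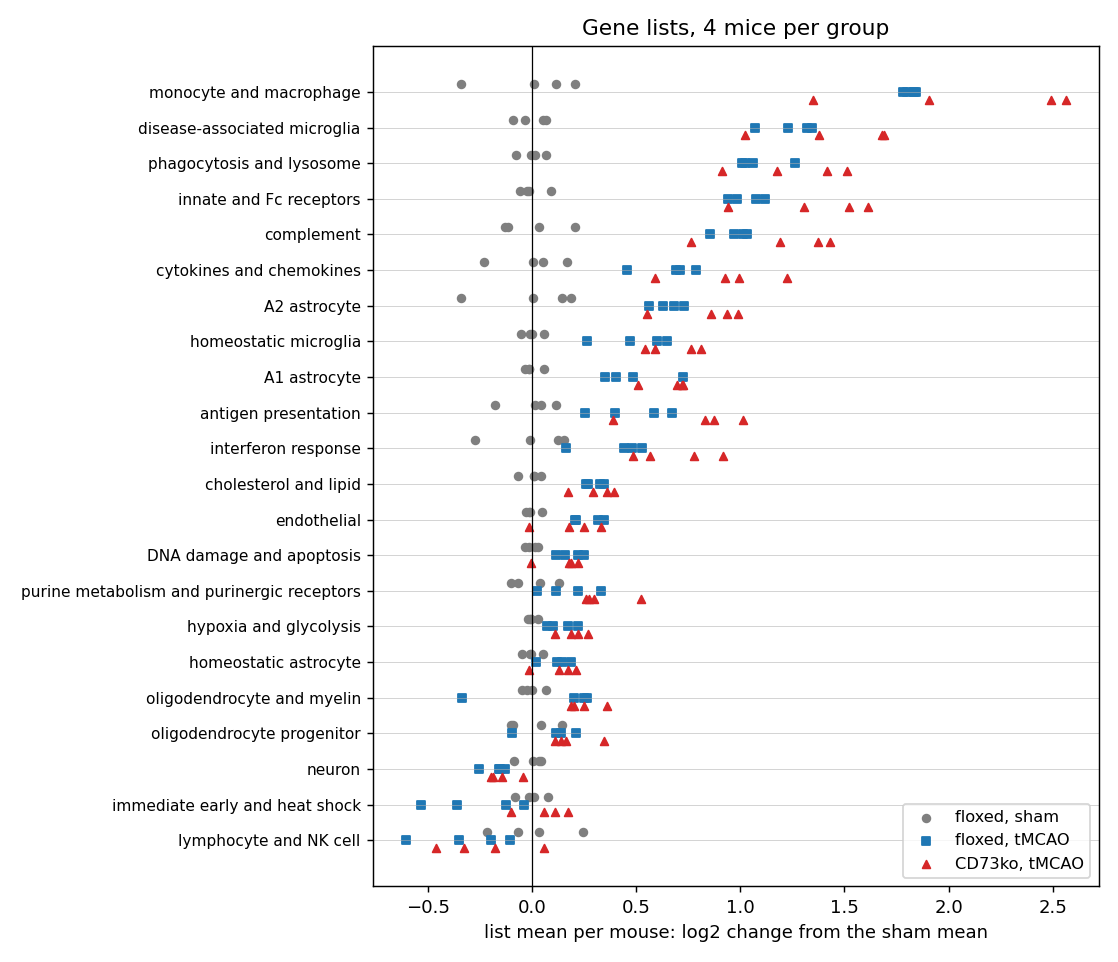
Mean log2 change from the sham mean over the measured members of each of the 22 gene lists tested (x axis), one point per mouse, 4 mice per group. The microglial, macrophage and complement lists of both tMCAO groups lie to the right of the shams, and 3 of the 4 CD73ko mice lie to the right of the 4 floxed tMCAO mice in lists such as the innate and Fc receptors. The lowest CD73ko mouse lies to the left of all 4 floxed tMCAO mice in lists such as disease-associated microglia and complement.

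The second comparison, of CD73ko with floxed mice after tMCAO, asked how the response differed between the genotypes. No gene passed the threshold. The 5 genes with the smallest p were all higher in CD73ko mice by these estimates: the log2 fold change was 0.65 (95% interval 0.27 to 1.02) for Psmb8, 0.77 (95% interval 0.31 to 1.23) for Cst7, 0.69 (95% interval 0.24 to 1.14) for Tlr7, an endosomal receptor of single-stranded RNA, 0.60 (95% interval 0.20 to 1.00) for the immediate early gene Fos and 0.35 (95% interval 0.11 to 0.59) for Adrb1. Their adjusted p-values were 0.747 each by edgeR's quasi-likelihood test. Among these 5, only Adrb1 had 4 mice in each group that did not overlap, at 118 ± 5.5 against 92.2 ± 4.06 normalised counts (mean ± SD, n = 4 mice each). Of all 757 genes, 29 did not overlap in this comparison, where chance gives 2.86% of genes, so this separation does not set Adrb1 apart. Spp1 stood at 5004 ± 2801 normalised counts in CD73ko and 3722 ± 351 in floxed mice (mean ± SD, n = 4 each).

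Camera at its preset correlation called 10 lists between the genotypes, none of which held with an estimated correlation, in fry or in the exact test of list means. It placed 9 lists higher in CD73ko mice: antigen presentation (adjusted p = 0.00396), innate and Fc receptors (0.00396), immediate early and heat shock genes (0.00481), cytokines and chemokines (0.0063), disease-associated microglia (0.00774), interferon response (0.0115), phagocytosis and lysosome (0.0139), homeostatic microglia (0.0246) and complement (0.0325). The endothelial list was lower (adjusted p = 0.0325). The differences of the list means per mouse were 0.30 log2 units for antigen presentation, 0.32 for innate and Fc receptors, 0.32 for immediate early and heat shock genes, 0.27 for cytokines and chemokines, 0.28 for interferon response and -0.08 for endothelial genes. They were 0.20 for disease-associated microglia, 0.22 for complement, 0.18 for homeostatic microglia and 0.17 for phagocytosis and lysosome. With an estimated correlation the values were adjusted p = 0.317 for antigen presentation, innate and Fc receptors, immediate early and heat shock genes, cytokines and chemokines, interferon response and endothelial genes, adjusted p = 0.493 for homeostatic microglia and complement, and adjusted p = 0.508 for disease-associated microglia and for phagocytosis and lysosome. No list passed fry (smallest adjusted p = 0.157) or the exact permutation test of list means (smallest adjusted p = 0.419). In 3 of 4 CD73ko mice the innate and Fc receptor mean lay above all 4 floxed tMCAO mice. CD73ko replicate 1 lay below all 4 floxed tMCAO mice in disease-associated microglia (1.02 against a lowest 1.07) and complement (0.766 against 0.853). The 9 lists hold 96 different genes, since some stand in several lists. Adjusted over the list alone, 2 genes passed in each of the antigen presentation, innate and Fc receptor, and immediate early and heat shock lists, 1 in the A1 astrocyte list and 0 in the others. Without CD73ko replicate 3, 3 lists passed camera, and 7 of the 10 calls were lost, at adjusted p = 0.0586 for innate and Fc receptors, 0.0838 for interferon response and 0.102 for cytokines and chemokines. Disease-associated microglia were lost without CD73ko replicate 3 (adjusted p = 0.211) or CD73ko replicate 4 (0.18). Homeostatic microglia were lost without CD73ko replicate 3 (adjusted p = 0.186), CD73ko replicate 4 (0.114), flox tMCAO replicate 2 (0.0725) or flox tMCAO replicate 3 (0.0573). Complement was lost without CD73ko replicate 3 (adjusted p = 0.225), CD73ko replicate 4 (0.206), flox tMCAO replicate 1 (0.104) or flox tMCAO replicate 2 (0.111). Phagocytosis and lysosome was lost without CD73ko replicate 3 (adjusted p = 0.154), CD73ko replicate 4 (0.432), flox tMCAO replicate 1 (0.104) or flox tMCAO replicate 2 (0.111). The endothelial call was lost without CD73ko replicate 1 (adjusted p = 0.386), flox tMCAO replicate 2 (0.111) or flox tMCAO replicate 3 (0.057). Antigen presentation and immediate early and heat shock genes passed without any one of the 8 mice. With each sample centred on its median 10 lists were higher and none lower, so the endothelial call was lost there, and after quantile normalisation 7 were higher and 2 lower.

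Members of these lists had single-gene estimates such as B2m (0.30 ± 0.10), Fcgr1 (0.54 ± 0.17), Itgam (0.57 ± 0.20), Trem2 (0.45 ± 0.19) and Grn (0.35 ± 0.12) as log2 fold changes ± SE, none past the threshold. Of the purine list, 0 of 12 members passed, with P2ry12 (0.35 ± 0.20) and Adora2b (0.29 ± 0.21). Apart from the microglial and endothelial lists called above, the cell type lists did not pass camera. Among them were neurons (adjusted p = 0.956), oligodendrocytes and myelin (0.0656), homeostatic astrocytes (0.58) and monocytes and macrophages (0.113). The median, mean and camera direction differed in sign for homeostatic astrocytes, neurons, lymphocytes, hypoxia and glycolysis, and cholesterol and lipid genes, none of them called.

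edgeR called 0 of 757 genes in this comparison, with 47 genes at an unadjusted p under 0.05 (45 higher and 2 lower in CD73ko) against 37.9 that chance gives, and DESeq2 and limma also called 0. The 95% interval of the log2 fold change lay within ±1 for 703 genes (92.9%), and over the 32 genes named by rule the widest bound was 1.23, for Cst7. In simulated counts of this comparison with 200 of 757 genes changed, the same test recovered 76.1% of 1.5-fold, 94.0% of 2-fold and 98.5% of 4-fold changes. Each gene was drawn there independently of the others. With fewer changed genes the adjusted threshold is stricter, and no such setting was simulated. These rates therefore do not show that a few changes of this size would have been called.

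The third comparison set CD73ko mice after tMCAO against floxed sham mice, in which genotype and surgery differ together. Among genes above background in the shams, the largest rises were those of Lgals3 (3.84 ± 0.32), Spp1 (3.78 ± 0.35), Gpnmb (3.56 ± 0.40), Serpina3n (3.31 ± 0.35), Lyz2 (2.91 ± 0.40) and Cd68 (2.82 ± 0.20), as log2 fold changes ± SE. Cst7 reached 80.6 ± 27.9 normalised counts (mean ± SD, n = 4 mice) against a sham level not above background, a rise of at least 5.72-fold. Tgm1 and Msr1, also above background in 0 of 4 shams, were at least 6.95-fold and at least 3.66-fold higher, and Fcgr4, above background in 1 of 4 shams, at least 3.95-fold higher. Of the phagocytosis and lysosome list 12 of 13 members rose, of the disease-associated microglia 18 of 23, of the innate and Fc receptors 8 of 10, of the complement list 7 of 10, of the cytokines and chemokines 8 of 15, of the A1 astrocyte list 8 of 10 and of the homeostatic microglia 12 of 20. Of the monocyte and macrophage list 5 of 6 rose, of the antigen presentation list 5 of 7 and of the A2 astrocyte list 7 of 12, or 5, 6 and 8 adjusted over the list alone. For the lists before these the numbers adjusted over the list alone were 13, 18, 8, 7, 8, 8 and 13. The number of A1 astrocyte genes that rose was 4 without flox sham replicate 3, 4 without CD73ko replicate 2 and 4 without CD73ko replicate 3. Of the interferon response list 4 of 7 rose. Neuron genes fell for 7 of 23 members (11 adjusted over the list alone), with Gad1 (-0.28 ± 0.06), and the number that fell was 4 without flox sham replicate 1, 11 without CD73ko replicate 1, 2 without CD73ko replicate 2, 1 without CD73ko replicate 3 and 2 without CD73ko replicate 4. Among genes that fell and whose 2 groups did not overlap, the lowest fold changes were those of Cd4 (-0.68 ± 0.20), Rasgrp1 (-0.40 ± 0.07), Cntnap1 (-0.35 ± 0.08), Dnm3 (-0.32 ± 0.06), Slc8a1 (-0.32 ± 0.05), Serpini1 (-0.32 ± 0.09), Dock3 (-0.31 ± 0.07), Unc80 (-0.31 ± 0.06) and Drd1 (-0.30 ± 0.08), which encodes a dopamine receptor. The Serpini1 call was lost without CD73ko replicate 3 (adjusted p = 0.0634). The Drd1 call was lost without CD73ko replicate 3 (adjusted p = 0.0564). The Cd4 call was lost without flox sham replicate 1 (adjusted p = 0.0821) or CD73ko replicate 4 (0.0663).

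In this comparison edgeR called 172 genes, 122 higher and 50 lower, of which 70 and none changed at least 2-fold; 1 of the 172 was not above background. Of the 70, 14 were above background in fewer than 3 shams, and 11 of the 14 were at least 2-fold higher against the background limit. The split was 102 and 119 with median centring, 101 and 109 centred on the housekeeping genes and 80 and 147 after quantile normalisation, which moved the median of all genes by -0.11 on the log2 scale. The number of calls was 110 without CD73ko replicate 3, and 267 without flox sham replicate 4 and flox tMCAO replicate 3. Camera called 11 lists, 10 higher and the neuron list lower; none held with an estimated correlation (adjusted p = 0.109 to 0.265). List means per mouse differed for 15 lists by the exact permutation test, and for 0 without flox sham replicate 3.

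Both tMCAO groups changed in much the same genes relative to the shared shams. The 96 genes higher in both include Lgals3, Spp1, Gpnmb, Cd68, C1qa and Gfap, and 37 genes were lower in both, among them Rasgrp1, Gad1 and Slc8a1; none moved in opposite directions. Independent lists of these sizes would share 17.2 higher and 3.96 lower genes. Over the 757 genes, which are not independent replicates, the 2 sets of log2 fold changes had a correlation of 0.958, where unchanged groups against the same 4 shams gave 0.521 on average and at most 0.637 in 100 simulations. Their covariance was 0.333 against a simulated 0.0174, a difference of 0.316. The simulations drew each gene independently of the others, so their highest value may be too low for mice whose genes vary together. With the shams split 2 and 2, so that the comparisons shared no library, the correlation was 0.794 to 0.899. In these splits 62 to 70 genes were higher in both and 4 to 10 lower in both. The lists of lower genes were shorter there, 22 to 49 genes in floxed and 15 to 42 in CD73ko tMCAO. The 3.96 above belongs to the longer lists and is no reference for these splits. The number lower in both was also 85 with median centring, 73 centred on the housekeeping genes and 85 after quantile normalisation. It was 22 without flox sham replicate 2, 67 without flox sham replicate 4, 58 without CD73ko replicate 1, 17 without CD73ko replicate 2, 14 without CD73ko replicate 3 and 18 without CD73ko replicate 4.

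**Figure D3:**
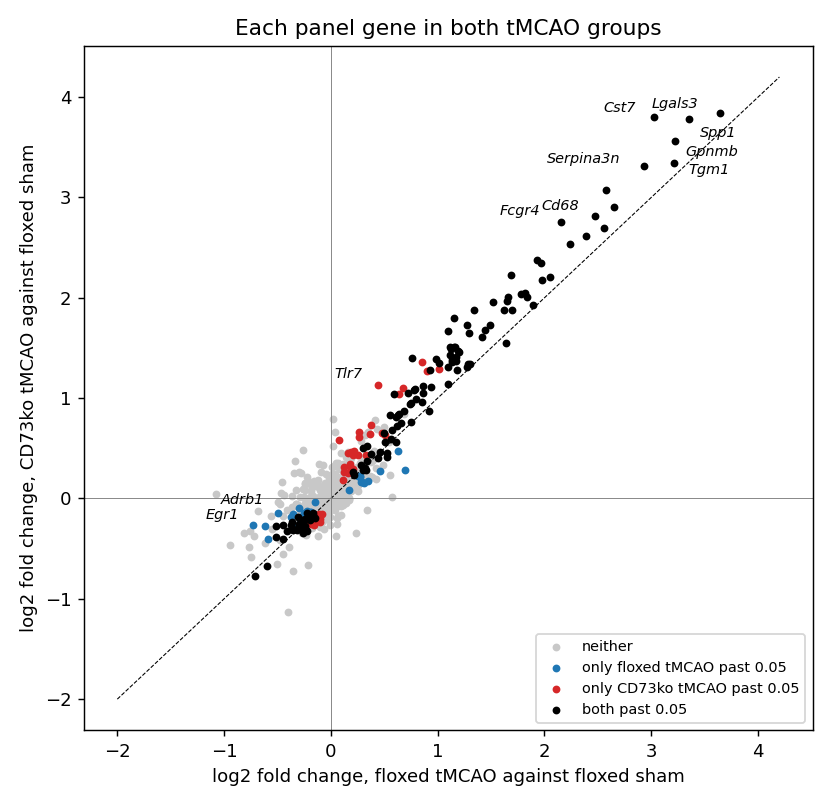
Log2 fold change of each of the 757 genes against floxed sham mice in floxed tMCAO (x axis) and CD73ko tMCAO mice (y axis); colours give which of the 2 comparisons passed an adjusted p of 0.05, and the dashed line marks equal changes. The points follow that line (correlation 0.958), and a gene coloured for one comparison alone is not thereby shown to differ between the genotypes, since 0 genes passed that test.

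The size of the response was measured per mouse as the slope of its log2 changes on the mean changes of the other 7 tMCAO mice. All changes were taken from the floxed sham mean, so in CD73ko mice the slope mixes surgery with genotype. The slope was 0.92 ± 0.08 (SD, n = 4) in floxed and 1.04 ± 0.24 (SD, n = 4) in CD73ko mice. The difference of 0.129 was within the spread between mice (exact two-sided permutation p = 0.343, smallest possible p = 0.0286). The 4 CD73ko mice ranged from 0.728 to 1.28 and the 4 floxed mice from 0.855 to 1.02. The difference was 0.23 without CD73ko replicate 1, 0.084 without CD73ko replicate 3 and 0.055 without CD73ko replicate 4.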

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

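The tests on the oligodendrocyte genes of flox tMCAO replicate 3 were chosen after the result was seen, and those on flox sham replicate 4 before it. Each measure below was set apart because, in one group of 4 mice, the distance of the highest or lowest mouse to its nearest neighbour took up an unusually large share of the group's range. This held for 16 of 338 groups examined, where chance gives 16.9.

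The total count of flox sham replicate 4 was 293589 against a mean of 810819 in the other 3 shams (gap share 0.915). Lower depth as the whole cause of its distance from the other shams was argued against: with all shams thinned to one total, the lowest chi-square per degree of freedom of a pair with this mouse was still 2.79 times the highest of a pair without it. A higher background share was argued against as well, since the 252 genes of lowest level differed from the 252 of highest level by -0.0416 in median log2 difference from the other shams, where background would raise the low ones. The positive controls of this library were at 0.306 and its endogenous total at 0.362 of the other shams, so the lower total went with lower counts of the assay's own spiked controls. What else sets this mouse apart stays open, and no biological explanation was tested, since the labels give this mouse no difference from the other shams.

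The oligodendrocyte and myelin list of flox tMCAO replicate 3 had a mean of -0.33 against 0.24 in the other 3 mice (log2, gap share 0.895). Scaling of the library was argued against, since the housekeeping genes of this mouse lay 0.0635 above those of the other 3 while its list mean differed by -0.57. A lower share of oligodendrocytes in the tissue taken could fit the 12 of 14 members that were lower than in each of the other 3 mice, with Ugt8a at -1.28 and Ermn at -0.84 (log2 differences). It stays open because Mbp (0.02) and Plekhb1 (0.04), also abundant, were not lower. In the same mouse 13 of 20 homeostatic microglia genes were below all 3 others and 4 above them. Its distance was not limited to these lists. Over all genes, pairs with this mouse had a chi-square per degree of freedom of 15.0 to 17.6. Pairs of the other 3 floxed tMCAO mice had 1.73 to 4.31, and pairs of CD73ko mice 3.01 to 18.7. The cause of this wider distance was not tested.

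The purine metabolism and purinergic receptors list had a mean of 0.52 in CD73ko replicate 3 against 0.28 in the other 3 mice (log2 change from sham, gap share 0.844). The A1 astrocyte list had a mean of 0.51 in CD73ko replicate 1 against 0.71 in the other 3 mice (log2 change from sham, gap share 0.863). Vim was at 9.25 in flox sham replicate 4 against 8.74 in the other 3 (log2 normalised count, gap share 0.900). Unc80 was at 10.48 in flox sham replicate 4 against 10.29 in the other 3 (log2 normalised count, gap share 0.85). Tspo was at 5.08 in CD73ko replicate 1 against 5.85 in the other 3 (log2 normalised count, gap share 0.897). Plekhb1 was at 11.66 in flox tMCAO replicate 4 against 11.77 in the other 3 (log2 normalised count, gap share 0.885). Hpgds was at 6.83 in flox tMCAO replicate 4 against 6.55 in the other 3 (log2 normalised count, gap share 0.876). Hmox1 was at 6.28 in CD73ko replicate 1 against 7.62 in the other 3 (log2 normalised count, gap share 0.911). Gfap was at 10.23 in flox sham replicate 4 against 9.73 in the other 3 (log2 normalised count, gap share 0.964). Entpd1 was at 6.65 in flox tMCAO replicate 2 against 6.94 in the other 3 (log2 normalised count, gap share 0.882). Egr1 was at 9.83 in CD73ko replicate 4 against 10.51 in the other 3 (log2 normalised count, gap share 0.953). Cntnap1 was at 9.07 in CD73ko replicate 3 against 9.24 in the other 3 (log2 normalised count, gap share 0.892). Bcas1 was at 10.06 in flox tMCAO replicate 3 against 10.39 in the other 3 (log2 normalised count, gap share 0.898). Adrb1 was at 6.45 in flox tMCAO replicate 4 against 6.57 in the other 3 (log2 normalised count, gap share 0.848).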

How the results depend on the processing

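The block on the replicate number was planned; DESeq2's size factors in edgeR, limma on log2(count + 1), the background filter, the thinned libraries with their losses by level and the fit without flox sham replicate 4 and flox tMCAO replicate 3 were chosen after the data were seen. Under the tools, scalings and filters tried, the calls of floxed tMCAO against sham stayed between 120 (all libraries thinned to the lowest total) and 205 (those 2 mice left out), apart from stricter thresholds, which gave 96 at an adjusted p of 0.01 and 84 at 1.5-fold. For CD73ko tMCAO against sham they gave 99 and 95, and leaving out those 2 mice gave 267 (the cause was not tested); the other settings gave 129 to 227. CD73ko against floxed tMCAO gave 0 genes under every setting run.

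With an estimated correlation camera called 0 lists in floxed tMCAO against sham, 0 in CD73ko against floxed tMCAO and 0 in CD73ko tMCAO against sham; fry, which asks another question, called 0 in the second and 19 in the third. The list means of floxed tMCAO against sham gave 0 lists centred on the housekeeping genes, since the discrete exact test passes only when 13 lists reach its smallest p. Genes lower in both tMCAO groups numbered 85 with median centring, 73 centred on the housekeeping genes, 85 after quantile normalisation and 7.17 on average with the shams split 2 and 2, where the correlation was 0.862; smaller sham groups are part of the construction of the last 2 values, and the cause was not tested for the scalings. In CD73ko tMCAO against sham, quantile normalisation turned the log2 fold change of Cspg4 from 0.43 to -0.0826 (adjusted p = 0.498, range over its settings 0.00842 to 0.548) and that of Adora1 from 0.10 to -0.366 (adjusted p = 0.0377, range 0.0377 to 1.000); the cause was not tested.

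Leaving out each mouse in turn gave 125 to 206, 0 to 0 and 110 to 229 called genes in the 3 comparisons in the order above of floxed tMCAO against sham, CD73ko against floxed tMCAO and CD73ko tMCAO against sham, 8 to 12, 3 to 12 and 11 to 12 lists, and 0 to 16, 0 to 0 and 0 to 18 list means. It gave a correlation of 0.942 to 0.960, 80 to 106 genes higher and 14 to 67 lower in both, and a difference in response size of 0.0550 to 0.230. Over all alternatives for named genes, a call was lost in 146 of the values of floxed tMCAO against sham and 179 of those of CD73ko tMCAO against sham, and gained in 25 and 46. For lists, calls were lost in 25, 47 and 11 values and gained in 8, 16 and 16 values of the 3 comparisons in the same order.

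With the replicate number as a block, 145, 0 and 146 genes and 8, 10 and 11 lists passed, and 92.7% of intervals of CD73ko against floxed tMCAO lay within ±1. Mice of one number deviated together with correlations between -0.23 and 0.19, and not every mouse matched its own number best, so the numbers do not pair the mice. The authors' normalised tables were not run as an alternative, because their samples could be given to no mouse. With every library thinned to the lowest total, 120, 0 and 132 genes passed. Among the 252 genes of lowest level 19 of 52 calls of floxed tMCAO against sham and 22 of 65 of CD73ko tMCAO against sham were lost there, and among the 252 of highest level 19 of 63 and 8 of 58.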

Other observations

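The tests on the immune lists of CD73ko mice, on the spread between mice and on genes outside the lists were chosen after the result was seen; the other splits of the mice were planned. The genes in this and the next paragraph stand in no list and were chosen after their values were seen. Of the 167 genes called in floxed tMCAO against sham mice, 78 stood in no list, 32 higher and 46 lower, and 54 of these were also called in CD73ko tMCAO against sham. Among those that rose were the complement C4 genes, counted together under a name that matched no list member, C4a/b (1.65 ± 0.18, log2 fold change ± SE as for the genes that follow) and the scavenger receptor gene Stab1 (1.34 ± 0.22). The myeloid transcription factor gene Spi1 (1.20 ± 0.23) rose, as did Aif1 (1.19 ± 0.27), which encodes the microglial marker IBA1, and Tspo (1.18 ± 0.23), which encodes the translocator protein used to image glial activation. Hpgds (1.13 ± 0.17), a prostaglandin D synthase gene, Pros1 (1.12 ± 0.19), which encodes the bridging protein S, the protease gene Klk6 (1.01 ± 0.24) and the transcription factor gene Stat3 (0.66 ± 0.11) rose too. The edgeR adjusted p of these 9 genes was at most 0.00665, and no call was lost without any one of the 8 mice.

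Among the 46 that fell were Drd1 (-0.37 ± 0.08), of a dopamine receptor, and Adcy5 (-0.37 ± 0.05), of an adenylyl cyclase, the calcium pump gene Atp2b2 (-0.37 ± 0.07) and the sodium-calcium exchanger gene Slc8a1 (-0.31 ± 0.05). Their calls also held without any one of the 8 mice. Over the 96 genes higher in both tMCAO groups, the median SD between mice was 0.219 in floxed and 0.331 in CD73ko mice (log2 values, n = 4 each), and it was larger in CD73ko for 68 of them; this difference was not tested.

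The 9 immune and stress lists placed higher in CD73ko than in floxed mice after tMCAO were examined further. That they rest on flox tMCAO replicate 3 alone was argued against, since 8 of the 9 passed camera without that mouse. Homeostatic microglia did not (adjusted p = 0.0573), the A1 astrocyte list passed instead (adjusted p = 0.00175), and 9 lists passed in all. This does not show that they rest on no single mouse, since only 3 lists passed without CD73ko replicate 3. Co-regulation of a list's genes between mice is a candidate explanation that could not be decided here. None of the 10 calls held once the correlation was estimated from the data. The same setting also called 0 lists in both comparisons with sham, so its result does not single out co-regulation. At the preset correlation, simulated counts of unchanged, independently drawn genes gave 0 lists. Splits of the real mice that balanced the genotypes gave up to 9. Such numbers therefore arose without a genotype contrast, which does not show that they did so in the real split. A larger overall response to tMCAO in the CD73ko mice stays open: the 126 genes that rose after tMCAO had a median log2 difference of 0.18 between the genotypes and were higher in CD73ko for 106 (exact two-sided permutation p = 0.229, 4 mice each), while the 85 that fell had a median of 0.0196 (exact p = 0.686), and a larger response would lower these. The genotype itself may act on these genes. With 4 mice per group, fry and the exact test of list means did not set it apart from the spread between mice. As no CD73ko sham was compared, a genotype difference present without tMCAO could not be told from one in the response.

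Chance was examined by regrouping the 8 mice of each comparison into all 35 splits of 4 and 4. For floxed tMCAO against sham the real split called 167 genes and the highest other 0, so 1 split, the real one, gave that many. For CD73ko tMCAO against sham the real split called 172 and the highest other 72, again with 1 split as large. Both counts argue against chance for the genes. They do not exclude it, since 1 of 35 is the smallest share that such splits can give. For CD73ko against floxed tMCAO the real split called 0 genes, so each of the 35 splits gave at least as many and the count says nothing of chance. The highest other split called 15. It set CD73ko replicate 1 and flox tMCAO replicates 1, 2 and 3 against the other 4 mice. Their response slopes were 0.728 to 0.928, against 0.991 to 1.28 in the other 4. The slopes come from the same counts, so they are no separate test of this split. The number of lists passing camera could not decide on chance. With the real split included, 4 splits gave as many as the 11 of floxed tMCAO against sham (highest other 12). In the same way 3 gave as many as the 10 of CD73ko against floxed tMCAO (highest other 11). For CD73ko tMCAO against sham 9 gave as many as its 11 (highest other 13). Every other split with as many exchanged only 1 mouse of each group, so it kept part of the real contrast. Splits with 2 mice of each genotype on either side hold no genotype contrast. In CD73ko against floxed tMCAO these balanced splits gave 1 to 9 lists. Nearly as many lists as the 10 of the real split could thus pass camera without that contrast. The list means per mouse argued against chance in both comparisons with sham. The exact permutation test was passed by 16 lists (adjusted p = 0.0393) and 15 lists (adjusted p = 0.0419). Each of these stood at the smallest p that the test can give, 0.0286, and some lists share genes, so chance is not excluded. Disease-associated microglia lay between 1.07 and 1.34 in floxed tMCAO and between -0.09 and 0.07 in sham mice (log2). These numbers of lists were 0 in the first without any one sham mouse and 0 in the second without flox sham replicate 3, as the adjusted value passes only when 13 lists reach the smallest p.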
